A study of Mus musculus with 36 samples.

How the data were processed

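RNA was measured in dissected mouse gut at embryonic days E10.5, E12.5 and E14.5, from embryos labelled wild type or Ret null and female or male. Each of the 12 groups held 3 libraries, 36 in all. Per the labels, the strain was C57BL/6J, poly(A) RNA was selected with oligo dT beads, libraries were made with TruSeq reagents and sequenced paired end on a HiSeq 2000. Per the submitters' processing notes, Picard, TopHat2, Cufflinks and Cuffdiff were used with the mm10 genome; their versions, settings and order are not given in the sources used here.

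The deposited files give 1 gene-level FPKM value (fragments per kilobase of transcript, scaled to sequencing depth) per gene and library, with the authors' interval around it, per the file headers. Each file held 23847 gene entries with 23361 distinct names. FPKM summed to 404022 to 497295 per library, and 12578 to 13644 genes reached 1 FPKM. Whether the authors scaled libraries to each other is not given in the sources used here. Read counts were not analysed; the width of the authors' intervals corresponded to 4.85 to 40.9 M fragments per library. At E10.5 it was 13.6 to 17.7 M in wild-type females, 6.85 to 7.48 M in wild-type males and 6.72 to 10.9 M in the libraries labelled Ret null, so depth went with the group in the genotype comparison within females and in that between the sexes. It was 17.4 to 40.9 M at E12.5, and at E14.5 6.17 to 8.06 M in the libraries labelled Ret null and 4.85 to 6.76 M in wild type. Within E14.5 females it was 7.08 to 8.06 M labelled Ret null and 4.85 to 5.13 M in wild type, so depth went with the group there too. In the comparisons of stages in wild type depth went with the stage. The files of the E10.5 females labelled Ret null differed in form: 0% of their FPKM values lay outside their own interval against 4.80 to 24.7% in the other libraries. How these files came to differ is not given in the sources used here. Start positions were read as counted from 0, since 12231 of 21913 genes then equalled the RefSeq start against 721 otherwise, and are given here counted from 1.

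Labels were checked with Ret, Xist and Y-linked genes. Agreement between the libraries of a group was compared with the counting noise that the fragment numbers imply, over genes with 50 to 2000 fragments. In 4 of 36 replicate pairs the spread was 0.900 to 1.07 times that noise and 0.280 to 0.693% of genes lay beyond 3 SD; in the other pairs the spread was 1.04 to 3.26 times the noise and 1.59 to 37.8% of genes lay beyond 3 SD. Such close pairs (E10.5 females labelled Ret null 1 and 2, E10.5 wild-type females 1 and 2, E10.5 wild-type males 3 and 4, E12.5 wild-type females 1 and 2) cannot be treated as separate embryos on these values, so each pair was averaged and counted as 1 sample, which leaves 32 samples. This rule (spread of at most 1.1 times the noise and at most 1% of genes beyond 3 SD) was set after the data were seen and departs from the fixed design, which counted every library; results with every library counted stand in the closing section as an alternative.

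Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and a mean-variance trend. Genes at 1 FPKM or more in at least 3 samples of a fit were tested, and genes without an OK status in any library of the fit were left out. Each stage was fitted on its own with 4 group means (genotype by sex). The genotype contrast was averaged over the sexes, and contrasts within each sex, the genotype-by-sex interaction and male against female wild type came from the same fit. Stage comparisons in wild type and genotype-by-stage interactions came from 1 fit of all libraries with 12 group means. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed; all tests were two-sided. The labels do not say whether libraries of a group came from separate embryos, so p-values measure the spread between these samples, which may be technical. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

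Before the data were examined, 45 gene lists were fixed, 3 of them of sex-linked genes. The others covered the enteric nervous system, signalling pathways, disease genes, gut wall, neighbouring tissues, other cells, body position and cell state. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists, and again with a correlation estimated per list. Member counts are given with adjustment over all genes and adjusted over the list alone. Genes within 10 Mb of Ret (chromosome 6, 118151748 to 118197744) were compared with all others by a two-sided Fisher's exact test across genes, since a targeted allele can carry flanking sequence.

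Named genes followed a rule fixed before the data were examined: Ret; per genotype or stage comparison up to 8 rising and 8 falling genes with the largest log2 fold change among those called with the same sign in both sexes; up to 5 each way between the sexes; up to 5 with the smallest adjusted p per interaction; up to 4 members with the smallest p per list described; the 3 smallest p where nothing passed. Small RNAs and symbols with more than 1 entry were left out of the rankings. The same rule was applied to the repeat without the libraries labelled Ret null that express Ret.

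Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, median-ratio scaling, a block for replicate number, a fit on all 36 libraries or on the 24 of both stages, windows of 5 and 20 Mb, an estimated correlation per list, and leaving out each sample in turn. Chosen after the data were seen were leaving out the libraries labelled Ret null with Ret at 1 FPKM or more, leaving out libraries whose sex genes go against the label, counting every library as its own sample, and removing trends on GC content and transcript length at E14.5. Results were set against up to 100 other splits of the same samples. The pipeline was tested on simulated data of the same shape with 100 genes changed by a log2 of 1 and 100 by a log2 of 2: 90 to 99 and 97 to 100 were recovered across the 7 comparisons, with 7 to 15 false calls, and a list shifted by 0.5 was found in each with 0 other lists called. The changed genes were drawn from the more highly expressed ones. Simulated genes varied independently, so this does not measure false list calls or recovery where genes vary together, as in the real samples.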

Results

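Gut from wild-type and Ret null mouse embryos was compared at 3 stages (E10.5, E12.5, E14.5). Ret encodes the receptor tyrosine kinase through which GDNF acts on the neural crest cells that build the enteric nervous system, so its own RNA is given first.

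Ret RNA lay between 2.11 and 13.3 FPKM in the 18 libraries labelled wild type and between 0.0111 and 0.0587 FPKM in 11 of the 18 libraries labelled Ret null. The other 7 libraries labelled Ret null held 4.74 to 6.49 FPKM: E10.5 females 1, 2 and 3 (5.37, 4.74 and 5.76 FPKM), E12.5 male 2 (6.12 FPKM), E14.5 females 1 and 3 (6.49 and 5.76 FPKM) and E14.5 male 1 (6.03 FPKM). A neuronal marker separated the same libraries at E14.5. Tubb3, a tubulin of neurons, stood at 47.4, 56.7 and 56.8 FPKM in the 3 libraries labelled Ret null with Ret, at 0.786 to 4.54 FPKM in the 3 without and at 20.1 to 59.1 FPKM in the 6 labelled wild type. Each genotype comparison is therefore given with the libraries as labelled and again without those 7, an alternative chosen after the data were seen. As that choice rests on Ret itself, the fall of Ret there only restates it. Ret is the receptor of enteric neural crest cells, so the choice can also favour libraries with fewer of those cells. In 4 pairs of libraries (E10.5 females labelled Ret null 1 and 2, E10.5 wild-type females 1 and 2, E10.5 wild-type males 3 and 4, E12.5 wild-type females 1 and 2) the spread between the values was 0.900 to 1.07 times the sampling noise, within a limit of 1.1 set after the data were seen. Each pair was averaged and counted as 1 sample. Sex-linked RNA went against the label in 4 libraries: E10.5 female 3 labelled Ret null (Xist 0.911 and Ddx3y 13.5 FPKM), E10.5 male 1 labelled Ret null (Xist 66.1 and Ddx3y 0 FPKM) and E12.5 wild-type females 1 and 2, which had both (Xist 49.1 and 52.2, Ddx3y 4.91 and 4.98 FPKM).

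**Figure D1:**
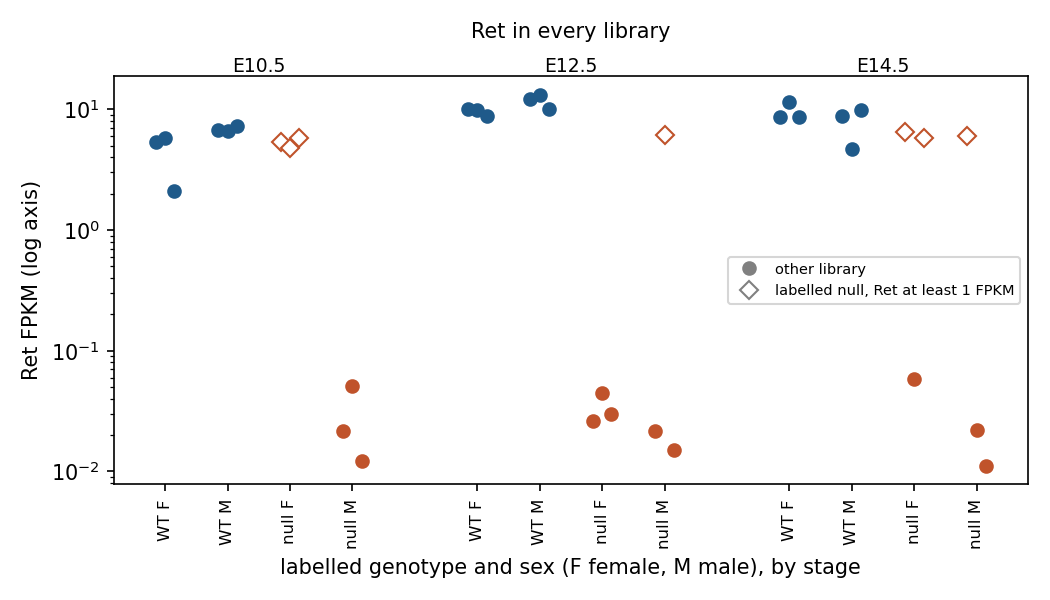
Ret in FPKM on a log axis for each of the 36 libraries, grouped by stage, genotype label and sex. Of the libraries labelled Ret null, 7 lie between 4.74 and 6.49 FPKM and 11 between 0.0111 and 0.0587 FPKM.

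At E10.5 smooth muscle genes were higher in the libraries labelled Ret null (5 samples) than in wild type (4 samples). Myh11, smooth muscle myosin heavy chain, averaged 22.4 ± 7.31 FPKM (mean ± SD) against 3.39 ± 2.67 FPKM, a log2 fold change of 2.58 (SE 0.225, adjusted p = 0.00229). Actg2, an enteric smooth muscle actin, rose from 20 ± 15.1 to 83.8 ± 13.8 FPKM (2.34, SE 0.191, adjusted p = 0.00179), and Cnn1, a calponin that binds actin in smooth muscle, from 4.29 ± 2.31 to 17.3 ± 3.41 FPKM (1.86, SE 0.148, adjusted p = 0.00179). Mylk, the kinase that phosphorylates myosin light chain, rose by a log2 of 2.0. Of the 15 tested members of the smooth muscle list 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 0.96 and adjusted p = 1.58e-08 by camera, or adjusted p = 0.284 with an estimated correlation. In mean log2(FPKM + 1) the list stood at 3.96 to 4.07 in libraries labelled Ret null with Ret and 4.11 to 4.26 in those without. Wild type held 2.58 to 3.58 at E10.5 and 3.66 to 4.84 at E12.5. Tissue of a later stage and an effect of genotype cannot be told apart for such genes. Genes called in females did not as a set follow the wild-type male change between these stages, but that test cannot decide (flagged results below).

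Epithelial and hedgehog genes rose in the same comparison. In the gut epithelium list 13 of 22 members rose and 0 fell (16 and 1 adjusted over the list alone, median 0.62, adjusted p = 8.43e-08; adjusted p = 0.421 with an estimated correlation). Its members with the smallest p included Cldn7, a tight junction protein (8.21 ± 1.46 to 18 ± 3.73 FPKM, log2 fold change 1.0), and Epcam, an epithelial adhesion molecule (20.2 ± 2.01 to 44.5 ± 7.86 FPKM, 1.07). Cdx2, an intestinal transcription factor (0.88), and Spint2 (0.60) rose too. In the hedgehog list 4 of 13 members rose (7 adjusted over the list alone), among them the ligands Shh (5.87 ± 1.32 to 15.3 ± 3.07 FPKM, 1.21) and Ihh (1.41) and the transcription factor Gli1 (0.88). The enterocyte and goblet cell list (6 of 11 rose, median 0.84) and the gut mesenchyme list (6 of 14 rose, 8 adjusted over the list alone, median 0.54) were also called higher. So were the interstitial cell of Cajal list (3 of 7 rose, median 0.49), the anterior Hox list (2 of 13 rose and 1 fell, median 0.48), the neural tube list (2 of 3 rose) and the pancreas list (1 of 6 rose, median 0.75). Markers of heart were lower (3 of 6 members fell, median -1.11, adjusted p = 0.0433), with Myl7 at -1.19, Tbx5 at -1.02 and Tnni1 at -1.79. So was the posterior Hox list (1 of 12 fell, median -0.46, adjusted p = 0.0125; Hoxc9 -1.20). The liver list had a median of 0.06 overall and -1.56 within females, with 0 of 13 members called. With an estimated correlation 0 of the 39 lists tested at E10.5 were called (lowest adjusted p = 0.284 with an estimated correlation). The count of 11 lists called was 7 without female 3 labelled Ret null and 17 without wild-type male 5.

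Among single genes, Cym, which encodes chymosin (0.206 ± 0.128 to 9.09 ± 5.22 FPKM, log2 fold change 2.53), Lgals2 (2.02), the globin gene Beta-s (1.93) and Sfrp5, a secreted Wnt antagonist (1.80), completed the 8 largest rises. The largest fall was in Hbb-bh1, an embryonic globin (608 ± 475 to 76.3 ± 24 FPKM, -2.58, SE 0.284, adjusted p = 0.00389). Per library Hbb-bh1 was 49.8 to 107 FPKM in the E10.5 libraries labelled Ret null. Wild type held 133 to 1090.6 FPKM at E10.5 and 19.5 to 252 FPKM at E12.5, so a later stage cannot be told apart from genotype here either. Among the other falls were the following. Cst9 (-1.97), the homeobox gene Alx1 (-1.71), the troponin gene Tnni1 (-1.79), Mme (-1.76), Shisa3 (-1.58) and Rxfp2 (-1.43) fell too. Ret itself averaged 5.43 ± 2.33 FPKM in wild type and 2.18 ± 2.96 FPKM in the libraries labelled Ret null (-1.23, SE 0.198, adjusted p = 0.0153), with 0.50 in females and -2.96 in males. The call for Ret was lost in 4 of 17 alternatives, among them the one without wild-type male 5. Those for Shisa3, Tnni1, Cym and Lgals2 were lost in 12 of 17, 11 of 17, 10 of 16 and 10 of 17 alternatives.

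In all, 1091 of 13165 genes changed at E10.5, 739 upward and 352 downward, with 3713 at an unadjusted p under 0.05. Within females 996 genes changed (600 up, 396 down) and within males 14 (13 up, 1 down). Without the libraries whose sex genes go against the label (female 3 and male 1 labelled Ret null), the female count fell to a small part of this and the male count rose (closing section). Without female 3 alone the female count stayed within 1.5 times of 996. By limma 0 genes had a genotype-by-sex interaction (2459 at an unadjusted p under 0.05); the smallest p belonged to Timm8a1 (0.91), Ret (-3.46) and Cartpt, a neuropeptide precursor (-5.12), each at adjusted p = 0.072. The interaction count was 140 without wild-type females 1 and 2, 5 and 6 without female 3 or male 1 labelled Ret null, and at most 1 otherwise. Leaving out 1 sample gave 601 genes without females labelled Ret null 1 and 2. It gave 348, 422 and 417 without males labelled Ret null 1, 2 and 3, 283 without wild-type males 3 and 4, and 179 without wild-type male 5. In females the count was 267 without females labelled Ret null 1 and 2 and 311 without wild-type female 3. In males it was 22, 4 and 0 without males labelled Ret null 1, 2 and 3, 7 without wild-type males 3 and 4 and 1 without wild-type male 5.

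Without the 3 Ret-expressing libraries only males remained at E10.5 (3 labelled Ret null against 2 wild-type samples), and 68 of 13037 genes changed, 59 up and 9 down. Galanin (Gal), a neuropeptide of enteric neurons, and Ret were among the 9 that fell (-2.08, SE 0.301, adjusted p = 0.0479, and -2.96, SE 0.284, adjusted p = 0.0140). The others named by size were Gm3893 (-1.36), Tbc1d4 (-0.89), Akr1e1 (-0.85), Dpf3 (-0.81), Frmd4b (-0.58) and Zfhx4 (-0.56). The smooth muscle genes Myh11 (1.91, adjusted p = 0.0614), Actg2 (1.44, adjusted p = 0.0765) and Mylk (1.49, adjusted p = 0.0651) lost their calls and Cnn1 (1.46, adjusted p = 0.0479) kept it, with 2 of 15 members of that list rising. The calls for Hbb-bh1 (-1.31), Cst9 (-3.31), Alx1 (-1.24), Tnni1 (-1.61), Mme (-1.90), Shisa3 (-1.53), Rxfp2 (-1.73), Lgals2 (1.63) and Beta-s (1.501) were lost as well. Rises were led by Barx1, a transcription factor of stomach mesenchyme (4.78, SE 0.697, adjusted p = 0.0491), Cym (3.33), Nepn, a proteoglycan (3.20), Sfrp5 (2.50), the zinc finger gene Zfp534 (1.80), the endoderm factor Foxa2 (1.74), Nkx6-3 (1.74) and Masp2 (1.72). In mean log2(FPKM + 1) the stomach list stood at 1.34 to 1.49 in these males labelled Ret null and at 0.395 to 0.460 in wild-type males. More stomach in the dissected tissue and an effect of genotype cannot be told apart for such genes. The enteric neuron list had a median of -0.93 with 0 of 27 members called (adjusted p = 8.33e-09; adjusted p = 0.612 with an estimated correlation), while with the libraries as labelled its median was 0.10 and 2 of 28 members rose (Crmp1 0.69, Tagln3 0.30). The neural crest progenitor list likewise had a median of -0.82 with 0 of 13 members called (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.612 with an estimated correlation), against -0.10 with 3 of 15 rising (Ednrb, Gfra1, Sox2) as labelled.

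At E12.5, with the libraries as labelled, enteric neuron and neural crest genes were called lower as lists and not as single genes. By limma 1 of 13182 genes changed (1115 at an unadjusted p under 0.05). It was the microRNA gene Mir3096b (10.4 ± 6.08 FPKM in wild type, listed at 0 in the libraries labelled Ret null), chosen after its values were seen. The count of 1 was 34 without male 2 labelled Ret null, 4 without wild-type female 3, 2 without female 1 labelled Ret null, wild-type females 1 and 2 or wild-type male 3, and 0 without any other sample. Ret averaged 10.9 ± 1.77 FPKM in wild type (5 samples) and 1.04 ± 2.49 FPKM in 6 libraries labelled Ret null (-3.02, SE 0.459, adjusted p = 0.255). The enteric neuron list had a median of -0.56 with 0 of 28 members called (4 lower adjusted over the list alone, adjusted p = 5.31e-09; adjusted p = 0.474 with an estimated correlation). The neural crest progenitor list had a median of -0.65 with 0 of 14 called (7 lower adjusted over the list alone, adjusted p = 3.99e-08; adjusted p = 0.307 with an estimated correlation). The neurotransmitter list was called lower by camera with a mean of -0.13 (adjusted p = 0.0408; adjusted p = 0.707 with an estimated correlation), although its median was 0.08.

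Leaving out male 2 labelled Ret null, the 1 library with Ret, gave 34 of 13121 genes, 0 up and 34 down. Ret fell to 0.0277 ± 0.0112 FPKM in 5 libraries (-3.49, SE 0.0802, adjusted p = 2.94e-07). The largest other falls were in genes of enteric neurons, their precursors and glia, led by Cartpt (14.4 ± 4.35 to 1.58 ± 0.911 FPKM, -2.59, SE 0.260, adjusted p = 0.00741) and the peptide gene Cck (10.9 ± 4.75 to 1.21 ± 0.660 FPKM, -2.44, adjusted p = 0.0121). Gal (-2.17), the nicotinic receptor subunit Chrna3 (-2.01), Mab21l1 (-1.96) and Sox10, a factor of neural crest and glia (to 2.24 ± 1.05 FPKM, -1.86, adjusted p = 0.0198), fell as well. Mir3096b, chosen after its values were seen, kept its call. In the enteric neuron list 3 of 28 members fell (17 adjusted over the list alone, median -0.84, adjusted p = 1.44e-17; adjusted p = 0.336 with an estimated correlation). These were Tagln3 (-0.89), the RNA-binding protein Elavl4 (-1.74) and the filament protein Ina (-1.59). In the neural crest progenitor list 4 of 14 fell (8 adjusted over the list alone, median -0.61, adjusted p = 4.28e-13; adjusted p = 0.205 with an estimated correlation), among them Foxd3 (-1.33), Sox8 (-1.14) and Sox10. Among the glia and Schwann cell list 2 of 6 fell, and among neuropeptides 2 of 6.

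Other lists called at E12.5 with the libraries as labelled had 0 members past the threshold over all genes. Higher were endothelium (median 0.31), extracellular matrix (0.36), Wnt (0.24), gonad and adrenal (0.47), smooth muscle (0.35), enterocyte and goblet cell (0.54), erythroid (0.48), liver (0.46) and posterior Hox (0.56). Lower were cell cycle (-0.08), glia and Schwann cell (-0.19), anterior Hox (-0.19), neuropeptide (-0.42), Hirschsprung disease genes (-0.07) and the Ret regulatory network (-0.36). With an estimated correlation 0 of 40 lists were called (lowest adjusted p = 0.307 with an estimated correlation). Within females and within males limma called 0 genes (1007 and 453 at an unadjusted p under 0.05), and 0 had a genotype-by-sex interaction (304 at an unadjusted p under 0.05). There Bcl2l12 (0.46), Car11 (-0.74) and Snapc1 (-0.52) had the smallest p, each at adjusted p = 0.989. Without male 2 labelled Ret null 15 genes were called in males, with 1 without male 3 labelled Ret null. In females 67 were called without female 1 labelled Ret null, 4 without wild-type female 3 and 2 without wild-type females 1 and 2.

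**Figure D2:**
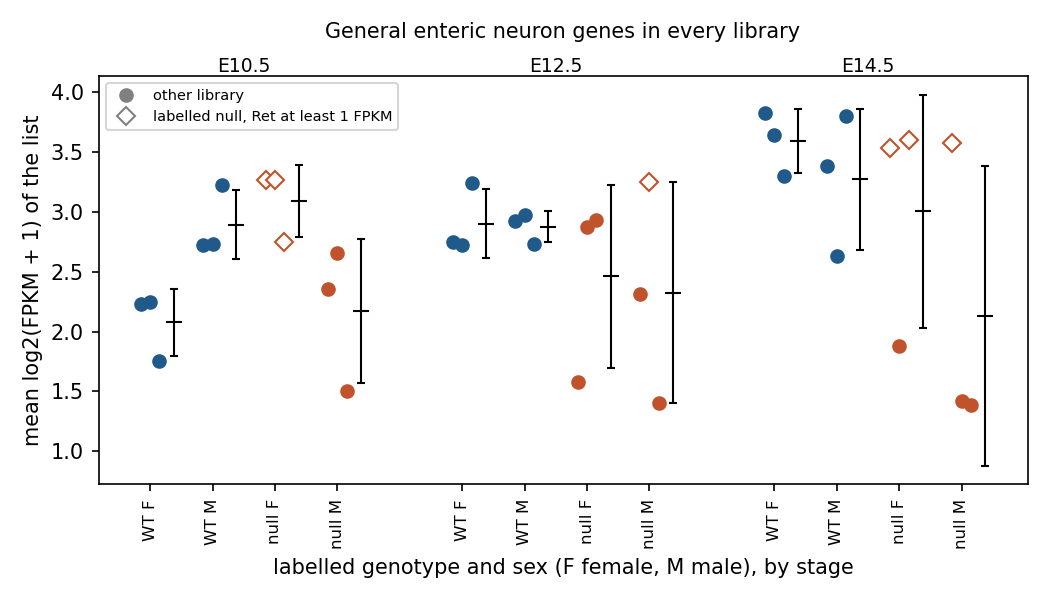
Mean log2(FPKM + 1) over the enteric neuron list for each library, by stage, genotype label and sex, with bars for mean ± SD of each group. Open diamonds mark the 7 libraries labelled Ret null with Ret at 1 FPKM or more, which at E14.5 hold 3.53 to 3.60 against 2.63 to 3.83 in wild type and 1.39 to 1.88 in the other libraries labelled Ret null.

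At E14.5 genes of mature epithelium and pancreas were lower in the 6 libraries labelled Ret null than in 6 of wild type. Tff3, a goblet cell peptide, fell from 92.0 ± 48.3 to 15.1 ± 7.23 FPKM (-2.55, SE 0.345, adjusted p = 0.00703). Spink4, a protease inhibitor of goblet cells, fell from 19.7 ± 12.4 to 1.43 ± 1.21 FPKM (-2.99, SE 0.451, adjusted p = 0.00828) and Adh1, an alcohol dehydrogenase, from 41.4 ± 52.1 to 2.13 ± 0.696 FPKM (-3.01, SE 0.651, adjusted p = 0.0180). The pancreatic enzyme genes Prss1 (-2.62), Try10 (-2.49) and Amy2b (-2.43) and the surface protein gene Ly6d (-2.32) also fell. In the enterocyte and goblet cell list 11 of 19 members fell and 0 rose (16 and 0 adjusted over the list alone, median -0.89, adjusted p = 4.67e-10; adjusted p = 0.565 with an estimated correlation). They included Guca2a, which encodes guanylin (-2.02), the apolipoprotein gene Apoc3 (-1.71) and Fabp1, a fatty acid binding protein (43.7 ± 29.3 to 9.35 ± 3.29 FPKM, -1.89). In the pancreas list 7 of 15 fell (9 adjusted over the list alone, median -1.11), and the list was not called with an estimated correlation. Its mean log2(FPKM + 1) was 5.13, 4.17 and 4.26 in wild-type females 2 and 3 and male 3. Wild-type female 1 (2.61) and male 1 (2.85) lay within the 2.18 to 3.11 of the libraries labelled Ret null, and wild-type male 2 (3.49) above it. The largest fall was in the pseudogene Atp6v0c-ps2 (42.2 ± 20.1 to 3.83 ± 5.92 FPKM, -4.09), whose reads can be shared with its parent gene.

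Glycolysis, macrophage and red cell genes were lower as well. In the hypoxia and glycolysis list 7 of 16 members fell (12 adjusted over the list alone, median -0.42, adjusted p = 1.51e-07), with the enzyme genes Pgk1 (495 ± 34.6 to 359 ± 26.4 FPKM, -0.46), Tpi1 (-0.51) and Ldha (-0.47). In the macrophage and leukocyte list 6 of 14 fell (12 adjusted over the list alone, median -0.39, adjusted p = 6.73e-07), with the lysozyme gene Lyz2 (26.8 ± 5.47 to 12.3 ± 2.91 FPKM, -1.06) and the complement genes C1qa (-0.70) and C1qb (-0.71). In the erythroid list 5 of 12 fell (median -1.34), with the adult globin Hbb-b2 (4190 ± 3080 to 764 ± 260 FPKM, -2.19) and Alas2, the heme synthesis enzyme of red cells (-1.85). Skeletal muscle (0 of 10 called, median -1.18), heart (0 of 8, -1.84), liver (0 of 11, -0.82) and endothelium (1 of 16 fell, -0.25) were called lower as lists. Single wild-type libraries stood apart in mean log2(FPKM + 1): heart was 7.51 in male 2 against 1.76 to 3.34 in the other wild-type libraries, and liver 6.51 in female 1 against 1.70 to 2.96. The erythroid list was 7.26 in female 1 and 6.49 in male 1 against 4.72 to 5.32 in the other wild-type libraries, which overlap the 4.45 to 5.11 of the libraries labelled Ret null. Also called lower were immediate early genes (3 of 13 fell and 1 rose, -0.21), extracellular matrix (2 of 18 fell, -0.19) and Notch (3 of 15 fell, -0.12). Each of these lists had an adjusted p of 0.565 or more with an estimated correlation.

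Hedgehog, gut mesenchyme and interstitial cell genes were called higher as lists at E14.5, where genes called higher overall went from 1504 to 727 with median-ratio scaling. In the hedgehog list 6 of 13 members rose (median 0.31, adjusted p = 0.00163; adjusted p = 0.565 with an estimated correlation). They included Shh (12.8 ± 2.63 to 19.7 ± 1.25 FPKM, 0.61) and its signal transducers Gli3 (0.63), Smo (0.25) and Ptch1 (0.53). In the gut mesenchyme list 4 of 14 rose (9 adjusted over the list alone, median 0.47, adjusted p = 0.0115; adjusted p = 0.565 with an estimated correlation), with Foxf1 (0.56), Bmp4 (0.39) and Pdgfra (0.56), while in the interstitial cell of Cajal list 3 of 7 rose (adjusted p = 0.0315; adjusted p = 0.565 with an estimated correlation), with the chloride channel gene Ano1 (0.37) and the receptor gene Kit (0.44). Among single genes the largest rise was in Nepn (3.04 ± 1.64 to 9.81 ± 1.42 FPKM, 1.54, SE 0.254, adjusted p = 0.00988). 4921507P07Rik (1.40), Tdh, a threonine dehydrogenase (1.36), Pet117 (1.14), A530016L24Rik (1.09), Ulbp1 (1.08), the RNA-binding protein gene Rbm46 (1.03) and Sesn3 (0.96) followed.

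Ret and neuronal genes varied within the E14.5 libraries labelled Ret null with the libraries as labelled. Ret averaged 8.70 ± 2.24 FPKM in wild type and 3.06 ± 3.33 FPKM in the libraries labelled Ret null (-1.81, SE 0.572, adjusted p = 0.0537). The enteric neuron list had a median of -0.83 with 1 of 29 members called, the secretogranin gene Scg2 (-0.86), and adjusted p = 1.05e-06 (adjusted p = 0.585 with an estimated correlation). The neurotransmitter list (2 of 13 fell, median -0.41) and the glia and Schwann cell list (2 of 8 fell, median -0.38; Entpd2 -0.91) were called lower. With an estimated correlation 0 of 41 lists were called, with adjusted p = 0.565 as the lowest.

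In all, 2175 of 13861 genes changed at E14.5, 1504 up and 671 down (69.1% up). With median-ratio scaling the split was 727 up and 884 down (45.1% up), so the share of higher genes rests on the scaling. Depth went with the group within females (7.08 to 8.06 M fragments labelled Ret null and 4.85 to 5.13 M in wild type), so it cannot be told apart from a difference in the tissue there. Within females 87 genes changed (40 up, 47 down) and within males 2 (1 up, 1 down); 0 genes had a genotype-by-sex interaction by limma (533 at an unadjusted p under 0.05). There Spon1 (-0.80), Gstm6 (1.57) and Trappc12 (0.46) had the smallest p, each at adjusted p = 0.98. The count of 2175 became 736, 906 and 3554 without females labelled Ret null 1, 2 and 3, and 1113, 778 and 669 without males labelled Ret null 1, 2 and 3. It became 1251 and 1296 without wild-type females 1 and 2, and 1194 without wild-type male 3. In females it became 6, 4 and 595 without females labelled Ret null 1, 2 and 3, and 28 and 633 without wild-type females 2 and 3. In males it fell to 0 without male 1 labelled Ret null or wild-type male 1 or 3, and to 1 without male 3 labelled Ret null or wild-type male 2.

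Without the 3 Ret-expressing libraries labelled Ret null, neuronal genes had most of the largest falls at E14.5 (3 libraries labelled Ret null against 6 of wild type). Tubb3 fell from 44.9 ± 14.7 to 2.19 ± 2.05 FPKM (-3.71, SE 0.321, adjusted p = 0.00321) and Stmn3, a stathmin of neurons, from 14.6 ± 3.85 to 0.342 ± 0.399 FPKM (-3.42, SE 0.229, adjusted p = 0.00193). Ret fell to 0.0306 ± 0.0249 FPKM (-3.19, SE 0.216, adjusted p = 0.00193) and Prph, peripherin, from 27.5 ± 9.64 to 2.15 ± 1.29 FPKM (-3.01, SE 0.325, adjusted p = 0.00576). Of the enteric neuron list 21 of 29 members fell and 0 rose (26 and 0 adjusted over the list alone, median -1.76, adjusted p = 2.74e-22; adjusted p = 0.474 with an estimated correlation). Of the neural crest progenitor list 7 of 14 fell (Tlx2 -2.82), and of the glia and Schwann cell list 4 of 8 (Fabp7 -1.50, Sox10 -1.65). Of the neurotransmitter list 4 of 13 fell (Chrna3 -2.51, Chrnb4 -1.91) and of the neuropeptide list 3 of 8 (Cartpt -2.53, Gal -2.15, Vip -2.05). Outside the nervous system Spink4 (-3.26), Tff3 (-3.10) and Atp6v0c-ps2 (-4.40) fell. Nepn (1.57), Tdh (1.41), Pet117 (1.32), the LIM homeobox genes Isl1 (1.29) and Isl2 (1.23) and Zfhx4 (1.07) rose. The calls for Adh1 (-3.04, adjusted p = 0.0826), Prss1 (-2.75, adjusted p = 0.0779), Amy2b (-2.53, adjusted p = 0.0576), Try10 (-2.49, adjusted p = 0.0975) and Sesn3 (1.09, adjusted p = 0.061) were lost with changes at least as large as before and larger SEs (0.302 to 0.966 against 0.215 to 0.651). Of the pancreas list 0 of 15 were called (6 lower adjusted over the list alone, median -1.24). In all 1182 of 13729 genes changed, 543 up and 639 down, with 101 in males (16 up, 85 down). In females 0 were called (2419 at an unadjusted p under 0.05 by limma), where 1 library labelled Ret null remained and was taken to vary like the other groups, so the counts of the sexes cannot be compared.

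Between stages, 23 genes were lower at both E12.5 and E14.5 without the Ret-expressing libraries, among 32 and 566 called in genes tested at both (1.41 expected, Fisher's exact p = 7.91e-25 across genes). They included Cartpt, Chrna3, Elavl4, Gal, Ret, Sox8 and Sox10. Gal and Ret were lower at E10.5 and E12.5 alike. At each stage the libraries labelled Ret null were kept for lacking Ret, itself an enteric gene. A shared fall of enteric genes can therefore be built in by that choice. Fisher's exact test also takes genes as independent, which genes of the same cells are not. Of the genes within 10 Mb of Ret 6 of 136 changed at E10.5 (4.41% against 8.33% elsewhere, Fisher's exact p = 0.116), 0 of 136 at E12.5 and 23 of 147 at E14.5 (15.6% against 15.7%, Fisher's exact p = 1). Without the Ret-expressing libraries 0 of 135, 0 of 136 and 18 of 147 changed, the last 12.2% against 8.57% elsewhere (Fisher's exact p = 0.136). The E10.5 count was 12 without female 3 labelled Ret null, 3 without male 1 labelled Ret null, 2 without wild-type males 3 and 4 and 1 without wild-type male 5. The E14.5 count was 11, 10 and 38 without females labelled Ret null 1, 2 and 3, 14, 9 and 9 without males labelled Ret null 1, 2 and 3, 14 without wild-type female 1 or 2 and 13 without wild-type male 3.

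**Figure D3:**
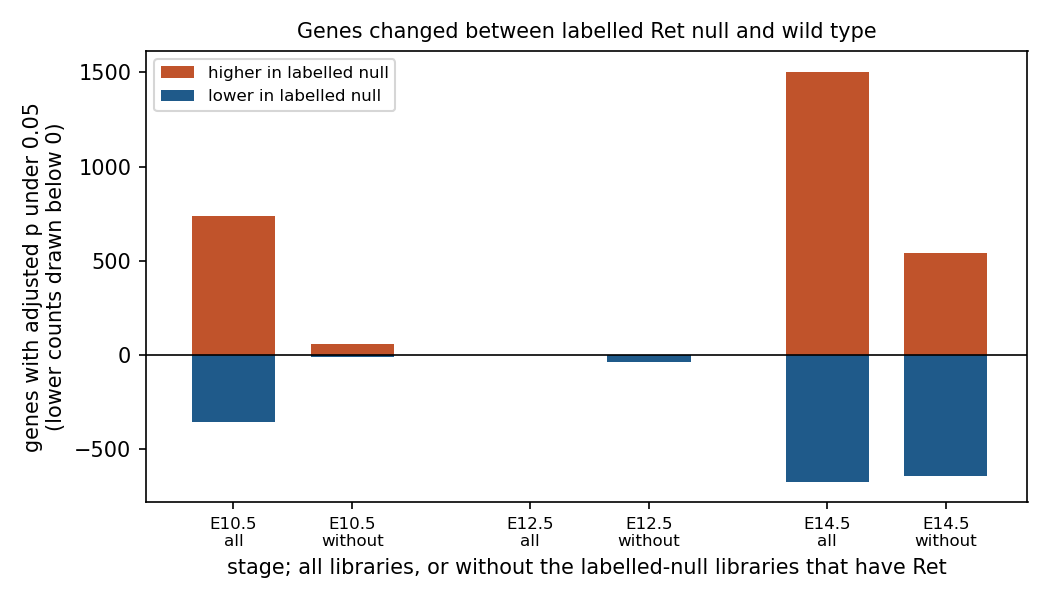
Number of genes called at an adjusted p under 0.05 at each stage, higher and lower in the libraries labelled Ret null, with the libraries as labelled and without those that express Ret. As labelled the totals are 1091, 1 and 2175, and without the Ret-expressing libraries 68, 34 and 1182.

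In wild type, smooth muscle and epithelial genes rose from E10.5 (4 samples) to E12.5 (5 samples) while genes of urogenital tissue and posterior Hox genes fell. Myh11 rose from 3.39 ± 2.67 to 28.8 ± 29.9 FPKM (2.48, SE 0.412, adjusted p = 0.00111), Actg2 from 20 ± 15.1 to 88.4 ± 69.6 FPKM (2.13) and Cnn1 by 1.84. In mean log2(FPKM + 1) of the smooth muscle list, wild-type male 2 of E12.5 stood apart at 4.84. The other wild-type libraries of E12.5 held 3.66 to 3.95 and those of E10.5 2.58 to 3.58. The Myh11 call was kept in 15 of 15 alternatives. Gfra1, the GDNF co-receptor, rose from 7.92 ± 4.81 to 29.1 ± 2.91 FPKM (1.95, SE 0.271, adjusted p = 0.000199). Tspan8 (2.15), Lgals2 (2.13), Fxyd3 (2.03) and the potassium channel gene Kcnj8 (1.89) also rose. The falls were led by Kctd14 (30.6 ± 18.6 to 0.929 ± 0.218 FPKM, -3.58) and the urogenital factor Emx2 (9.83 ± 3.51 to 0.501 ± 0.342 FPKM, -2.79). Wnt6 (-2.51), the gonadal and adrenal factor Nr5a1 (-2.43), Akr1cl (-2.34), Hoxc10 (-2.33), Alx4 (-2.21) and Hoxd9 (-2.16) fell as well. The smooth muscle list (9 of 17 rose and 1 fell, median 0.59) and the gut epithelium list (8 of 23 rose and 1 fell, median 0.51) were called higher. The mesonephros and kidney list (3 of 13 fell, median -1.19), the posterior Hox list (5 of 14 fell, median -1.31) and the gonad and adrenal list (2 of 14 fell, median -0.43) were called lower (lowest adjusted p = 0.351 with an estimated correlation). Urogenital tissue dissected along with the gut at E10.5 cannot be told apart from a change in the gut. In all 654 of 14321 genes changed, 394 up and 260 down, between stages that also differed in depth (6.85 to 17.7 M fragments at E10.5 and 22.8 to 30.8 M at E12.5 in wild type). The count was 308 without wild-type female 3, 335 without wild-type males 3 and 4 and 324 without wild-type male 5 of E10.5, and 303 without wild-type females 1 and 2 and 298 without wild-type female 3 of E12.5.

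From E12.5 to E14.5 in wild type (5 and 6 samples) pancreatic and absorptive genes rose most. Ctrb1, chymotrypsinogen B, went from 0.745 ± 0.582 to 583 ± 516 FPKM (7.93, SE 0.453, adjusted p = 1.31e-11) and Pnliprp1, a pancreatic lipase relative, from 1.90 ± 0.931 to 302 ± 226 FPKM (6.41). Ins2, an insulin gene, rose from 0.143 ± 0.0962 to 42.9 ± 33.9 FPKM (4.93) and Tff3 from 1.67 ± 1.71 to 92.0 ± 48.3 FPKM (5.22). Lypd8 (5.46), the urea cycle gene Cps1 (4.95), the colipase gene Clps (4.92) and Adamdec1 (4.71) followed. The falls were led by the embryonic globins Hbb-bh1 (131 ± 85.7 to 4.24 ± 4.08 FPKM, -4.60), Hbb-y (-3.69) and Hba-x (-3.51). Hmga2, a chromatin protein of early development (242 ± 15.7 to 46.9 ± 10 FPKM, -2.39), Fndc3c1 (-2.19), Nr1h5 (-2.10), Hsd11b2 (-2.04) and Saa2 (-2.03) fell too. Of the enterocyte and goblet cell list 18 of 20 rose (median 2.54), of gut epithelium 19 of 23 (1.34), and of pancreas 13 of 15 (2.62). Of extracellular matrix 16 of 18 rose (1.54) and of hypoxia and glycolysis 14 of 16 with 1 falling (0.81), while of the cell cycle list 14 of 24 fell (-0.24), with adjusted p = 0.578 as the lowest with an estimated correlation. In all 8431 of 14321 genes changed, 4439 up and 3992 down. Depth went with the stage (22.8 to 30.8 M fragments at E12.5 and 4.85 to 6.76 M at E14.5 in wild type), and its part in this count was not tested.

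The genotype difference itself differed between stages for 192 genes from E10.5 to E12.5 (78 up, 114 down) and for 2489 from E12.5 to E14.5 (1602 up, 887 down). In the first of these the smallest p belonged to the zinc finger genes Zfp534 (-1.57, SE 0.156) and Gm13154 (-0.92), and to Frmd4b (0.71), Akr1e1 (1.06) and Dpf3 (1.27). Zfp534 averaged 0.411 ± 0.124 FPKM in wild type and 3.89 ± 0.154 FPKM in the libraries labelled Ret null at E10.5. In the second they were Vprbp (-1.27, SE 0.106), Luc7l (0.37), the hormone gene Sct, which encodes secretin (-2.46), Tff3 (-3.17) and Dcun1d4 (0.57). Enterocyte and goblet cell genes (9 of 20 lower, median -1.18), pancreas (9 of 15 lower, -1.25), endothelium (7 of 16 lower, -0.58) and macrophage genes (6 of 14 lower, -0.56) led the lists from E12.5 to E14.5 (adjusted p = 0.604 for each with an estimated correlation). Without the Ret-expressing libraries the count from E10.5 to E12.5 was 1 and from E12.5 to E14.5 was 2560. Both counts fell by over 1.5 times without the libraries whose sex genes go against the label, that of 192 to a small part (closing section). The count of 192 moved over 1.5 times without 15 of 20 samples and lay between 51, without female 3 labelled Ret null of E10.5, and 417, without female 1 labelled Ret null of E12.5. That of 2489 was 1426 and 1609 without female 3 and male 1 labelled Ret null, and 1646 and 1342 without wild-type females 1 and 2 and female 3, all of E12.5.

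Between the sexes in wild type, E14.5 differed in 7 of 13861 genes (4 higher and 3 lower in males). The Y-linked genes Eif2s3y (4.21), Ddx3y (3.54), Kdm5d (3.04) and Uty (2.07) were higher in males, and Xist, the RNA of X inactivation, (-5.99) and Eif2s3x (-0.74) were lower. At E12.5 2 genes differed, Xist (-5.90) and Eif2s3x (-0.59), where wild-type females 1 and 2 also had Y-linked RNA (Ddx3y 4.91 and 4.98 FPKM). At E10.5 1176 genes differed (509 higher and 667 lower in males), between groups that also differed in depth (13.6 to 17.7 M fragments in females and 6.85 to 7.48 M in males). Female 3 and male 1 labelled Ret null, whose sex-linked RNA goes against the label, share that fit. The count fell by over 1.5 times without them (closing section). Xist and the Y-linked genes were not among the genes named at E10.5, although they separated the sexes in wild type. Xist stood at 79.6 to 90.6 FPKM in wild-type females and 0.0768 to 0.118 FPKM in wild-type males. Ddx3y stood at 0.0402 to 0.0947 and 12.9 to 15.5 FPKM. The 2 libraries with sex-linked RNA against the label widen the spread of these genes in the shared fit. Secreted liver proteins were lower in males, with Afp, alpha-fetoprotein (library means of 506 FPKM in females and 3.80 in males, -6.72 over samples), Itih2 (-5.35), Serpina6 (-4.81), Fgb (-4.48) and Apom (-4.11). The gonadal hormone gene Amh (4.04), Ptgds (3.20), Cst9 (3.09), Aldh1a1 (2.70) and Cartpt (2.35) were higher. In mean log2(FPKM + 1) the gonad and adrenal list stood at 1.97 to 2.31 in wild-type males and 1.135 to 1.62 in wild-type females of E10.5. So neighbouring tissue in the libraries cannot be told apart from a sex difference of the gut. Cst9 was also among the falls in the libraries labelled Ret null at E10.5. This E10.5 count was 683 without wild-type females 1 and 2, 54 without wild-type female 3, 11 without wild-type males 3 and 4 and 0 without wild-type male 5, in groups of 2 samples each. The E12.5 count was 7 without wild-type females 1 and 2 and 1 without any 1 wild-type male, and the E14.5 count was 11 without wild-type female 2.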

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

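All tests in this part were chosen after the result was seen, except that of the E14.5 change against loss of Ret, which was set before.

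Ret RNA was present in 7 libraries labelled Ret null. Among the libraries labelled wild type, 0 had Ret under 1 FPKM, which argues against a swap with them. Relative to enteric markers, Ret stood at a mean log2 of -1.59 against wild type in the 3 such libraries of E10.5 (wild-type SD 0.543) and at -0.813 in the 1 of E12.5 (SD 0.223). Each lay below every wild-type library, which argues against wild-type RNA or tissue mixed into a null library there, and 1 working Ret copy under a null label would give such values. The 3 of E14.5 had a mean of -0.582 (SD 0.279), but female 1 (-0.44) lay within the wild-type libraries (lowest -0.45), so for E14.5 a mixture and 1 working copy cannot be told apart. With wild type set at 0 and the other libraries labelled Ret null at 1, the enteric neuron list stood at -0.0745 in the 3 of E14.5 (wild-type libraries reached 0.427), which argues against a null genotype that still makes Ret RNA. For E12.5 (-0.524, wild type up to 0.246) and E10.5 (-1.93, wild type up to 2.33) the other libraries labelled Ret null overlap wild type in that list, so this cannot be told apart and the genotype of all 7 stays open.

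Outside the enteric nervous system lists, many genes changed at E14.5. Library size factors differed by at most a log2 of 0.0957, and 1304 of 1503 rises and 647 of 665 falls exceeded that by more than 2 SE. Called genes lie several SE from 0 by selection, so most would pass this limit in any case. Some of the rises that lost their call with scaling passed it too, so it cannot decide on scaling. The calls for genes higher depend on scaling: with median-ratio scaling 726 of 1503 kept call and direction. In the 777 that lost it the median went from 0.257 (SE 0.0706) to 0.209 (SE 0.0709), since the shift of -0.045 took small rises under the threshold. Of the genes lower 662 of 665 kept call and direction, so those calls did not rest on that scaling. With trends on GC content and transcript length removed, 879 of 1503 higher and 413 of 665 lower genes kept call and direction, which argues against these as the whole cause. Of the 87 genes called in females 100% went against the wild-type male change from E12.5 to E14.5 (Spearman -0.574 across 13851 genes), which less mature tissue in the libraries labelled Ret null would give. With wild type at 0 and the libraries without Ret at 1, the 3 libraries labelled Ret null with Ret stood at a mean of -0.124 for 38 enteric genes and of 0.555 for 1143 genes outside the lists. For the latter none lay near that mean: female 1 and male 1 stood at 0.75 and 0.759, beyond every wild-type library left out of the calls (highest 0.368), and female 3 at 0.157, among them. As they split, loss of Ret and a difference of another kind cannot be told apart. FPKM summed to 404022 to 421851 in the E14.5 libraries labelled Ret null other than female 3 (497295), and to 448521 to 491231 in wild type. Values outside their own interval made up 8.50 to 10.6% in the libraries labelled Ret null and 4.80 to 6.81% in wild type. So the making of the files, or depth, cannot be told apart from a difference in the tissue either.

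In females at E10.5, 996 genes changed, and the files labelled Ret null differed in form from the others. Female 3 labelled Ret null also had sex-linked RNA against its label. Without the E10.5 libraries of that kind, female 3 and male 1 labelled Ret null, the count fell to a small part of this. Female 3 alone did not account for that fall: without it the count stayed within 1.5 times of 996. Both fits leave 1 sample of females labelled Ret null. With each wild-type female sample left out in turn, wild-type males differed from the left-out sample in the called direction for 86.6% of 827 and 91.3% of 311 genes. These calls rest on 1 wild-type female sample, taken to vary like the other groups. The wild-type female files also differed from the wild-type male ones in fragments (13.6 to 17.7 M against 6.85 to 7.48 M) and in values outside their own interval (12.4 to 16.1% against 6.06 to 6.63%). So files made by another procedure, or depth, cannot be told apart from a difference in the tissue. Of the genes called higher and lower, 53.7% of 600 and 33.1% of 396 went with the wild-type male change from E10.5 to E12.5. That change may not span the difference in females. In mean log2(FPKM + 1) of the enteric neuron list, E10.5 wild-type males stood at 2.72 to 3.22 and wild-type females at 1.75 to 2.25. Wild-type males of E12.5 stood at 2.73 to 2.97. So the test cannot decide on more mature tissue. All of the 13 tested liver markers (100%) were higher in wild-type females than in wild-type males, so liver tissue in the wild-type female libraries could account for some genes lower. For the genes higher (median 0.746) a smaller share of liver and other differences cannot be told apart, since scaling to the median gene would by itself put the median of all genes (-0.0107) near 0.

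Other splits of the same samples were set against the E10.5 counts. The 1091 genes changed stood against 17 in the highest other split, with 1 of 60 splits (the real one) as large, so the count is larger than chance gives. For the 6 genes near Ret (highest other 0, 1 of 60) the splits decide nothing, since none called over 17 genes in all, and the share near Ret was 4.41% against 8.33% elsewhere (Fisher's exact p = 0.116). The 11 lists called stood against 19, with 36 of 60 as large, so chance cannot be excluded for the list counts. For the genotype-by-sex interaction the count was 0 (highest other 1091), so all 60 of 60 were bound to be as large and the splits decide nothing.

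At E12.5, the 1 gene changed stood against 822 in the highest other split with 38 of 100 as large, which points to structure among the samples other than the genotype label. The 18 lists called stood against 22 (8 of 100), so chance cannot be excluded. For the interaction (highest other 822, 100 of 100 as large) and the genes near Ret (highest other 11, 100 of 100) the counts were 0, so the splits decide nothing. In males 0 genes stood against 2 (10 of 10 splits), with too few splits to say. Without male 2 labelled Ret null, 34 genes stood against 204, with 8 of 100 as large, so chance cannot be excluded for that count and sample structure is present there too.

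At E14.5, the 2175 genes changed stood against 236 in the highest other split, with 1 of 100 (the real one) as large. For the 23 genes near Ret (highest other 3, 1 of 100) the totals likewise set the counts, so the splits decide nothing. The 18 lists stood against 22 with 17 of 100 as large, so chance cannot be excluded for them. The interaction count was 0 (highest other 2796, 100 of 100 as large), so its splits decide nothing. The splits were too few to say for females (87 against 1, 1 of 10), males (2 against 1, 1 of 10) and the sexes in wild type (7 against 3, 1 of 10). Without the Ret-expressing libraries, 1182 genes stood against 51, with 1 of 40 as large.

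Between stages in wild type, 654 genes stood against 282 (1 of 60) and 8431 against 7757 (1 of 100). The genotype-by-stage count of 192 stood against 966, with 5 of 100 as large, so chance cannot be excluded. A split with several times the real count points to structure among the samples, and these splits can also carry the genotype difference of 1 stage. That of 2489 stood against 482, with 1 of 100 as large.

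A test for 1 sample far from the rest of its group (Dixon) marked 3 of 36 groups, where chance marks about 1 in 20. They were Ret in the E12.5 libraries labelled Ret null (male 2 at 6.12 FPKM, next 0.0451, ratio 0.995), the neurotransmitter list in E12.5 wild type (female 3 at 2.34, next 1.80, ratio 0.792) and the neural crest progenitor list in E14.5 wild type (male 2 at 2.55, next 3.00, ratio 0.755).

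The genotype difference itself differed between stages for 192 genes from E10.5 to E12.5, with Zfp534 at -1.57, Gm13154 at -0.923, Frmd4b at 0.71, Akr1e1 at 1.06 and Dpf3 at 1.27. From E12.5 to E14.5 it did for 2489, with Vprbp at -1.27, Luc7l at 0.374, Sct at -2.45, Tff3 at -3.17 and Dcun1d4 at 0.571.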

How the results depend on the processing

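The choices of scale, filter, fit, window and named genes were made before the data were examined. Counting each of 4 close pairs of libraries as 1 sample was set after, and leaving out libraries for Ret or sex genes, counting every library, and removing GC trends were added after as well. The cause of a difference was not tested unless stated.

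With a correlation estimated per list, 0 lists were called at E10.5, 0 at E12.5 and 0 at E14.5. A pseudocount of 0.1 gave 8 genes in E10.5 males, 1 in the E10.5 interaction with sex, 1 in E12.5 females, 1 in E12.5 males and 1 in the E14.5 interaction. With no filter on low values, E10.5 gave 625 genes, 1 in males, 1 in the interaction and 607 between the sexes. E12.5 then gave 2 in females, 1 in the interaction and 5 between the sexes, and E14.5 40 in females. Median-ratio scaling gave 12 genes in E14.5 males. Within 20 Mb of Ret 11 genes changed at E10.5, and within 5 Mb 2 at E10.5 and 14 at E14.5, as the window sets how many genes are counted.

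The fit on all 36 libraries, which has more residual degrees of freedom, gave 56 genes in E10.5 males, 31 in the interaction, 1802 between the sexes and 14 near Ret. At E12.5 it gave 2 genes, 2 in males and 0 between the sexes. At E14.5 it gave 4554 genes, 1516 in females, 2259 in males, 1 in the interaction, 3 between the sexes and 54 near Ret. On the 24 libraries of both stages the genotype-by-stage count from E10.5 to E12.5 was 301.

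Counting every library as its own sample, as the fixed design did, gave, at E10.5, 3774 genes, 4485 in females, 931 in males, 1917 in the interaction, 4323 between the sexes and 32 near Ret. It gave 0 genes at E12.5, 1829 from E10.5 to E12.5 in wild type and 769 for genotype by stage.

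With a replicate block, E10.5 gave 4 genes, 55 in females, 8 in males, 15 in the interaction, 19 lists and 0 genes near Ret, and the neural crest progenitor list was called in the other direction with a median of -0.32. Myh11, Actg2, Cnn1 and Mylk were not called at E10.5 with it. E12.5 gave 1 gene in females and 1 in the interaction, and E14.5 26 genes, 1 in females, 0 in males and 1 near Ret. Of 14 same-number pairs, 5 had a correlation over 0.1 (range -0.328 to 0.415). With so few samples per group these correlations are tied to one another. For E12.5 female 1 labelled Ret null they were 0.415 and -0.415 with the wild-type female samples. So they cannot show whether the numbers pair the samples, and the counts with a block stand as an alternative.

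Without the libraries labelled Ret null that express Ret, E10.5 gave 68 genes, all within males (68), and 0 near Ret, and the neural crest progenitor list (median -0.82) and the enteric neuron list (-0.93) turned downward. E12.5 gave 34 genes, 1 in females and 15 in males, and E14.5 1182, 0 in females (with 1 library labelled Ret null left) and 101 in males. The genotype-by-stage count from E10.5 to E12.5 was 1.

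Without the libraries whose sex genes go against the label, E10.5 gave 184 genes, 21 in females, 36 in males, 9 in the interaction, 519 between the sexes and 2 near Ret. E12.5 gave 2 genes, 2 in females, 1 in males, 1 in the interaction and 7 between the sexes. From E10.5 to E12.5 in wild type 264 genes changed, and genotype by stage gave 5 from E10.5 to E12.5 and 1473 from E12.5 to E14.5.

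A sample left alone in its group was taken to vary like the other groups. Leaving out 1 sample at a time gave, at E10.5, 179 to 1268 genes, 267 to 921 in females, 0 to 22 in males, 0 to 140 in the interaction, 0 to 683 between the sexes, 7 to 17 lists and 1 to 12 genes near Ret. At E12.5 it gave 0 to 34 genes, 0 to 67 in females, 0 to 15 in males, 0 to 3 in the interaction, 1 to 7 between the sexes, 14 to 22 lists and 0 genes near Ret. At E14.5 it gave 669 to 3554 genes, 4 to 633 in females, 0 to 2 in males, 0 to 1 in the interaction, 7 to 11 between the sexes, 14 to 21 lists and 9 to 38 genes near Ret. In wild type it gave 298 to 735 genes from E10.5 to E12.5 and 7450 to 8475 from E12.5 to E14.5, and for genotype by stage 51 to 417 and 1342 to 3563. The gut epithelium list at E12.5, not called with all libraries, had medians of -0.12 to 0.10 and was called lower, against its direction with all libraries, without male 3 labelled Ret null.

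Of 1406 values for named genes across all alternatives, 1246 kept their status (called or not called), 153 lost a call, 7 gained one and 0 reversed. Of 2156 for lists 1963 kept their status, 104 lost a call, 85 gained one and 4 reversed. Most lists were not called in the first place. A list called in neither setting counts as keeping its status, even where its direction turned. So these totals do not give the share of calls that were kept.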

Other observations

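Liver RNA differed between the groups at E10.5. Afp, alpha-fetoprotein of fetal liver, averaged 506 FPKM in wild-type females, 3.80 in wild-type males, 123 in females labelled Ret null and 119 in males labelled Ret null. Alb, albumin, averaged 109, 0.349, 73.5 and 58.1 FPKM, Trf, transferrin, 81.5, 8.82, 30.7 and 27.4 FPKM, and Fgb, a fibrinogen chain, 27.3, 0.307, 3.21 and 3.25 FPKM in the same order. Within females the liver list had a median of -1.56 with 0 of 13 members called (5 lower adjusted over the list alone, adjusted p = 0.00172; adjusted p = 0.601 with an estimated correlation). Within females the enteric neuron list had a median of 0.99, and 6 of 28 members rose (17 adjusted over the list alone, adjusted p = 4.54e-08; adjusted p = 0.601 with an estimated correlation).

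The Ret signalling and smooth muscle lists were not called at E14.5 with the libraries as labelled: 4 of 23 members rose and 1 fell (adjusted p = 0.946), and 3 of 18 rose and 1 fell (adjusted p = 0.984). The extracellular matrix list was called lower with 2 of 18 members falling (adjusted p = 0.0371; adjusted p = 0.658 with an estimated correlation). Single members of these lists were chosen after their values were seen. Gdnf, the ligand of the Ret receptor complex, rose by a log2 of 0.75 (adjusted p = 0.0169, and adjusted p = 0.0526 without the Ret-expressing libraries), and its co-receptor Gfra1 by 0.58 (adjusted p = 0.0261 and 0.161), at a stage where the genes called higher went from 1504 to 727 with median-ratio scaling. Eln, elastin, fell from 141 to 64.9 FPKM (-1.09, adjusted p = 0.012 and 0.0549) and the muscle filament gene Des fell by 0.53 (adjusted p = 0.00958 and 0.0162).

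With the libraries as labelled, 96 genes were higher at both E10.5 and E14.5 where 84.2 were expected (Fisher's exact p = 0.17 across genes), and 14 were lower at both where 14 were expected.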
